A study of Mus musculus with 6 samples.

How the data were processed

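H3K9me3 was measured by CUT&Tag in quadriceps femoris, with 3 Prr14-WT libraries (replicates 3, 4 and 8) and 3 Prr14-KO libraries (replicates 4, 5 and 7). Groups were taken from the genotype labels. Each library was taken to be a different mouse, which the labels do not state. The deposited table has 202553 non-overlapping regions shared by all 6 libraries. The submitters' processing notes name Trimmomatic, BWA, MACS2, deepTools, bedtools and DESeq2 1.6.3 and the build GRCm38, without their settings or order. Whether regions were called on pooled or single libraries, and whether positions count from 0 or 1, is not given in the sources used here, and positions are printed as the table gives them.

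Per the file headers, each library has a column of values that are whole numbers, read here as raw counts per region and deposited without scaling. The authors also deposited a normalised signal per library, which equals the count divided by a single factor per library, and it was used here only to read those factors. Per the file headers, the authors' log2 fold change is knockout over wild type, and its sign follows their normalised values. The authors' p-value and adjusted p-value were used as deposited, and 39271 regions have no adjusted p. The deposited score of each region runs from 1.30 to 2835, its meaning is not given in the sources used here, and it was not used in a test. Gene symbols, distances to start sites and annotation classes are those of the authors' table, which names 16587 symbols and leaves 681 regions without a symbol. Gene spans came from the RefSeq table of GRCm38.p6, the same build.

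Library totals ran from 4324444 to 4756133 counts, and the median standard error of a log2 fold change was 0.46 for a region, 0.22 for a gene sum and 0.07 for a bin. Counts were tested with edgeR 4.0.16 in R 4.3.3: features with low counts were removed with filterByExpr (minimum count 10, minimum total 15), leaving 153789 regions (75.9%), libraries were scaled by TMM, and a quasi-likelihood fit with robust weighting of the spread compared knockout with wild type. Benjamini-Hochberg adjusted p-values were taken over all features tested at each level, with a threshold of 0.05. The levels were single regions, sums of all regions the authors assign to a gene symbol, and sums over bins of 1 Mb by the midpoint of the region. Standard errors were derived from the fold change and its F statistic. Values given with SD are TMM-scaled CPM, or percent of a library's counts for shares. No spike-in is named in the labels, so a uniform gain or loss of the mark is scaled away.

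Gene lists were tested on gene sums with voom, fry and camera in limma 3.58.1, with adjustment over the 26 lists. Fry tests whether a list's genes move in a common direction, or change in either direction, without comparing them with other genes. Camera compares a list with other genes, and was run with a preset correlation of 0.01 and with an estimated correlation. The lists were slow fibre, fast fibre, embryonic and cardiac sarcomere, MEF2 and fibre type, myogenic, nuclear lamina with envelope and mechanotransduction, heterochromatin, oxidative, glycolytic, imprinted, germline, neuronal, and 7 lists of other cell types. Another 7 were families chosen by symbol: zinc finger, olfactory receptor, vomeronasal and trace amine receptor, clustered protocadherin, homeobox, cytochrome P450 with UGT and related clusters, and immunoglobulin and T cell receptor segments. Printed list medians and member values are from the edgeR gene sums, while the tests used voom values. Shares of counts per class and chromosome were compared by a two-sided exact permutation test over all 20 arrangements, which cannot give a p under 0.10. Classes of changed regions were compared by Fisher's exact test, two-sided, with adjustment over the 8 classes.

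The lists, tests, thresholds, alternatives and the rule for named genes were chosen before the data were examined, except where stated. The rule took, in each direction, regions past the threshold with all knockout values on one side of all wild-type values, the region with the smallest p for each symbol, up to 12, and filled to 6 with regions that did not pass. Symbols of gene models (Gm with digits, Rik and clone names) were passed over. Members of fixed lists that passed, Prr14 and Mef2c were added, and up to 6 bins of 1 Mb per direction were eligible. Gene models named in the text, the chromosome 13 cluster, the site on chromosome 5, the sums without regions past the threshold and the grouping of 4 dispersed sites were chosen after their values were seen.

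Alternatives were RLE size factors, library totals, loess offsets (span 0.3), DESeq2 1.42.0, limma-voom, other filters on low counts (any count, or a mean of 20), an adjusted p of 0.10, an added fold of 2, leaving out X and Y, leaving out regions under 500 bp, promoter and genic regions only for gene sums, bins of 100 kb, and leaving out each library in turn. Fits without robust weighting, fits with the log2 mitochondrial share of counts as a covariate, and gene lists without regions inside Esr1 were added after seeing the data. The same comparison was also run on every split of the 6 libraries into groups of 3. A correction for GC content was not run, since no genome sequence was used here.

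The tests of regions, gene sums and bins were run on simulated counts drawn with the means, spreads and library sizes of the real libraries. In each, 200 features were changed, and all features were drawn independently of each other. The tests of shares and classes were not simulated. Regions changed 1.5-fold, 2-fold and 4-fold were recovered in 0%, 7.46% and 51.5% of cases, with 4 wrong calls among 43. For gene sums the shares were 35.8%, 65.7% and 86.4%, with 8 wrong among 133, and for bins of 1 Mb 95.5%, 100% and 100%, with 14 wrong among 211. Changes were simulated in 2 lists, the 24 neuronal and the 5 fast fibre genes, the second and the larger folds being added after a first, smaller test. The shares and sums were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.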

Results

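H3K9me3, the histone mark of constitutive heterochromatin, was profiled in quadriceps femoris of Prr14-WT and Prr14-KO mice, with 3 libraries per genotype. The assay was CUT&Tag, in which a transposase tethered to the antibody-bound mark cuts and tags the DNA beside it. Prr14 encodes a protein of the nuclear lamina that binds the heterochromatin protein HP1, and the series title names muscle fibre identity, mechanotransduction and MEF2C as its subject. Over 202553 regions, the wild-type libraries held 4756133 counts in replicate 3, 4646568 in replicate 4 and 4636898 in replicate 8. The knockout libraries held 4707466 counts in replicate 4, 4340285 in replicate 5 and 4324444 in replicate 7. The labels give no batch, sex or litter. The replicate numbers read as mouse numbers, though the labels do not say that each library is a different mouse. The edgeR p-values below rest on the spread between libraries, estimated for each feature partly from all features. Those of Fisher's exact test compare regions and do not measure a spread between mice. The labels name no spike-in, and the scaling between libraries removes any change shared by all regions.

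Most regions lay far from genes. Of all regions, 68.1% were intergenic, 22.6% lay in introns and 3.80% within 1 kb of a transcription start site. The median width was 318 bp (quartiles 201 and 546 bp), and together the regions covered 85.4 Mb. The genes given the most regions were Cntnap5b (464 regions), Cdh8 (455), Pcdh9 (445), Csmd3 (438) and Pcdh7 (409). The 20 regions with the most counts, among them sites annotated to Tcp10c on chromosome 17, Gm10800 on chromosome 2, and Gm10718 and Gm10722 on chromosome 9, took between 7.46% and 8.19% of each library.

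Wild-type and knockout libraries resembled each other as much as libraries of the same genotype did. Across regions, which are not independent replicates, the mean correlation of log2 values was 0.659 within genotypes and 0.662 between them. Across bins of 1 Mb it was 0.991 within and 0.991 between. The share of tested regions whose 3 knockout values all lay on one side of the 3 wild-type values was 9.61%, where chance gives 10%. A region held 22.6 counts per library on average, and pairs of libraries differed by 2.47 to 2.99 times the variance that counting error alone gives.

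At the targeted gene, Prr14 on chromosome 7, the data held a single region, at 127475331 to 127476074 (GRCm38), inside the gene's span and annotated within 1 kb of a start site. Its counts were 10, 18 and 10 in wild-type replicates 3, 4 and 8, and 14, 56 and 54 in knockout replicates 4, 5 and 7. H3K9me3 at this region rose in the knockouts from 2.95 ± 1.11 to 10.3 ± 6.11 CPM, the scaled count relative to library size (SD, n = 3), by 1.79 on the log2 scale (SE 0.38, edgeR adjusted p = 0.0216). The groups overlapped, since knockout replicate 4 lay below wild-type replicate 4. The call was lost without wild-type replicate 3 (edgeR adjusted p = 0.679), wild-type replicate 8 (0.474), knockout replicate 5 (1.00) or knockout replicate 7 (1.00), and over 19 alternatives the adjusted p ran from 8.62e-05 to 1.00. DESeq2 and limma-voom did not call it (adjusted p = 1.00 and 0.988). Nor did an edgeR fit with the mitochondrial share as a covariate, added after seeing the data (adjusted p = 0.530). The gene sum, from this region alone, had a log2 change of 1.76 (SE 0.46) and an edgeR adjusted p of 0.30 among gene sums. Without knockout replicate 4 it passed, at 2.18 and an adjusted p of 0.000786. The part of Prr14 deleted in these mice is not given in the sources used here, so the counts do not check the genotype labels.

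At Mef2c, the muscle transcription factor gene named in the series title, 0 regions of the deposited table lay in its RefSeq span on chromosome 13, from 83504017 to 83667079. A change of the mark inside the gene was therefore not tested. The authors' annotation gives it 78 regions, of which 63 were tested, all of them intergenic, from 82650652 to 83926015. These regions lay outside the gene, the nearest of them starting at 83685898. None passed the edgeR test over all regions, which in simulated libraries recovered 7.46% of regions changed 2-fold. An unadjusted p under 0.05 was found in 6 of the 63, a larger share than the 3.84% over all tested regions. Log2 changes ran from -1.29 to 1.26, with a median of -0.03 over the 63. The gene sum was 376 ± 20.2 CPM in the wild types and 363 ± 8.50 in the knockouts (SD, n = 3). Its log2 change was -0.05, with a 95% interval from -0.19 to 0.10 (edgeR adjusted p = 1.00).

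The region comparison asks where H3K9me3 differs between Prr14-KO and Prr14-WT muscle. It found few differences, and these lay at a small number of places. They were exons of the oestrogen receptor gene Esr1, the distal ends of the X and Y chromosomes, and sites elsewhere. The latter lay in Ppp1r9a, Prr14 and Gm15446, or were intergenic and assigned to Ajap1, Adgrl2, Diaph2, Aptx and Gm10772. The Gm15446 and Gm10772 regions lay in longer stretches of lower counts, described below. Of 153789 regions tested, 20 passed an edgeR adjusted p of 0.05, 5 higher and 15 lower in the knockouts. Without adjustment 5903 regions had a p under 0.05 (3.84% of those tested), 3113 higher and 2790 lower. DESeq2 called 16 regions and limma-voom 17, of which 16 and 11 were among the 20. In simulated libraries of this depth the test recovered 7.46% of regions changed 2-fold and 51.5% of those changed 4-fold, so smaller changes at single regions were mostly not detectable with these libraries.

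**Figure D1:**
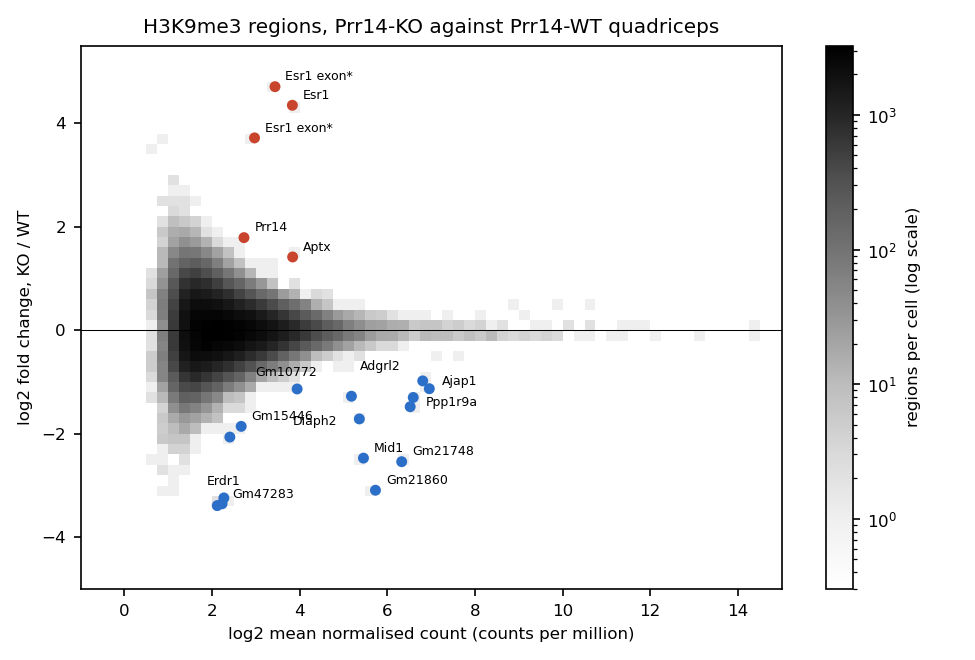
Log2 fold change of each tested region (knockout over wild type, vertical) against its log2 mean in CPM (horizontal), as a grey grid of regions per cell on a log scale, with the 20 regions past an edgeR adjusted p of 0.05 as points. The 5 red points are higher in the knockouts and the 15 blue points lower; each name is written at 1 point of that name, and "Esr1 exon*" stands for regions that the authors' annotation names Syne1 but that lie inside the Esr1 span.

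The strongest gains in counts lay in exons of Esr1, which encodes oestrogen receptor alpha, on chromosome 10 (span 4611989 to 5005633). A change of the mark itself at these exons was not tested. The region at 4856925 to 4857194 rose from 1.30 ± 1.04 to 27.2 ± 16.4 CPM (SD, n = 3), a log2 change of 4.35 (SE 0.33, edgeR adjusted p = 4.74e-36). A region at 5001186 to 5001420, named Syne1 by the authors' annotation but lying inside the Esr1 span, rose from 0.781 ± 0.759 to 20.9 ± 11.8 (log2 change 4.70, adjusted p = 9.86e-30). Another, at 4997828 to 4998013, also named Syne1 and inside Esr1, rose from 1.09 ± 0.723 to 14.6 ± 4.53 (log2 change 3.72, adjusted p = 2.56e-15). All 3 are annotated as exonic, and all were higher in each of the 3 knockout libraries than in any wild type. The 17 intron regions inside Esr1 summed to 46.6 ± 10.6 and 51.8 ± 6.74 CPM, a log2 change of 0.15 (exact permutation p = 0.60, two-sided). With limma-voom none of these exonic regions passed, at adjusted p = 0.146, 0.988 and 0.988.

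The other region that rose, apart from Prr14, was an intergenic site on chromosome 4, at 40596414 to 40597610, whose assigned start site is that of Aptx, a DNA repair gene, 105704 bp away. It went from 7.80 ± 2.30 to 20.8 ± 5.55 CPM (SD, n = 3), a log2 change of 1.42 (SE 0.25, edgeR adjusted p = 0.000163), and was higher in 3 of 3 knockouts. It did not pass without wild-type replicate 4 (adjusted p = 0.103) or knockout replicate 4 (0.181), over a range from 9.18e-06 to 0.181 in 19 alternatives. The next gains did not pass: a region named Mex3b inside Efl1 (log2 change 1.27, adjusted p = 0.173), a Tmprss12 exon (1.19, adjusted p = 0.429) and a Dip2c intron (1.22, adjusted p = 0.480).

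Counts fell at 4 single sites on chromosomes 3, 4, 6 and X, each among the well-covered regions, with all knockouts below all wild types. Whether the mark itself changed there was not tested. In an intron of Ppp1r9a, which encodes the actin-binding synaptic protein neurabin, the region at 4923777 to 4924243 on chromosome 6 dropped from 137 ± 23.7 to 55.7 ± 1.76 CPM (SD, n = 3), a log2 change of -1.30 (SE 0.15, edgeR adjusted p = 1.10e-13). An intergenic region assigned to Ajap1 on chromosome 4, at 153153035 to 153153554, dropped from 171 ± 28.7 to 78.0 ± 8.48 (log2 change -1.13, adjusted p = 5.72e-11); it lies 328884 bp from the Ajap1 start site, and RefSeq places it in the gene model Gm31055. On chromosome 3, at 149052475 to 149052935, an intergenic region assigned to Adgrl2, a latrophilin gene whose start site is 62150 bp away, dropped from 149 ± 16.9 to 75.5 ± 2.75 (log2 change -0.98, adjusted p = 2.26e-07). A region on X at 129056553 to 129056757, intergenic and assigned to Diaph2, dropped from 63.0 ± 7.98 to 19.2 ± 3.72 (log2 change -1.71, adjusted p = 2.06e-16); it lies 693087 bp from the Diaph2 start site, and RefSeq places it in 4930558G05Rik. The 60 other regions within 100 kb of these 4 sites summed to 482 ± 4.20 and 508 ± 17.8 CPM, a log2 change of 0.076 (exact permutation p = 0.10, the smallest that 3 against 3 allows). Most of this sum lay around the site assigned to Ajap1 (31 regions, 385 CPM in the wild types, log2 change 0.075), and the neighbours changed by -0.16 around the Ppp1r9a site (14 regions), 0.31 around that assigned to Adgrl2 (11) and 0.32 around that assigned to Diaph2 (4).

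Another 8 of the regions that fell lay at the distal ends of X and Y, around the pseudoautosomal region where the sex chromosomes pair. On X, the region at 169993733 to 169994941, annotated to an intron of Mid1, fell from 74.4 ± 11.5 to 13.4 ± 1.09 CPM (SD, n = 3), a log2 change of -2.47 (edgeR adjusted p = 1.42e-34). Beside it, at 169996410 to 169996635, a region assigned to Erdr1 fell from 8.75 ± 1.46 to 0.904 ± 0.310 (log2 change -3.24, adjusted p = 5.23e-06). RefSeq places neither region inside Mid1 or Erdr1. On Y, the 6 regions were assigned to Gm21860, Gm21748 and Gm47283, between 90737726 and 90813910, with log2 changes from -3.39 to -1.27. The Gm21860 region at 90741047 did not pass without wild-type replicate 3 (adjusted p = 0.447) or with DESeq2 (1.00), over a range from 5.67e-11 to 1.00 in 18 alternatives. Erdr1 and both Gm47283 regions did not pass with limma-voom (adjusted p = 0.988 each). The share of counts on Y below 90 Mb was 0.117% ± 0.00611 in the wild types and 0.117% ± 0.0124 in the knockouts (SD, n = 3).

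Of the regions that fell, the remaining 3 had the largest adjusted p. In an intron of Gm15446, a gene model on chromosome 5, the regions at 109934007 and 109935913 had log2 changes of -1.86 (edgeR adjusted p = 0.0177) and -2.06 (0.0229). Knockout replicate 7 held 0 counts in both, and without it neither passed (adjusted p = 1.00 and 1.00). The region at 109934007 was also lost without wild-type replicate 3 (0.144), 4 (0.0685) or 8 (0.999) or knockout replicate 5 (0.659), and the region at 109935913 without wild-type replicate 3 (0.900) or 4 (1.00) or with the mitochondrial share as a covariate, a fit added after seeing the data (0.14). DESeq2 (adjusted p = 1.00) and limma-voom (0.988) called neither. On chromosome 13, at 66268124 to 66269210, a region assigned to Gm10772, 41094 bp from its start site, dropped from 21.1 ± 1.01 to 9.60 ± 1.69 CPM (SD, n = 3), a log2 change of -1.13 (adjusted p = 0.0216). It did not pass without wild-type replicate 3 (0.50), 4 (0.396) or 8 (0.116), or knockout replicate 5 (1.00) or 7 (0.177). Across alternatives the adjusted p ran from 3.27e-06 to 1.00 for the region at 109934007, from 0.00259 to 1.00 for that at 109935913 and from 0.00769 to 1.00 for Gm10772.

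**Figure D2:**
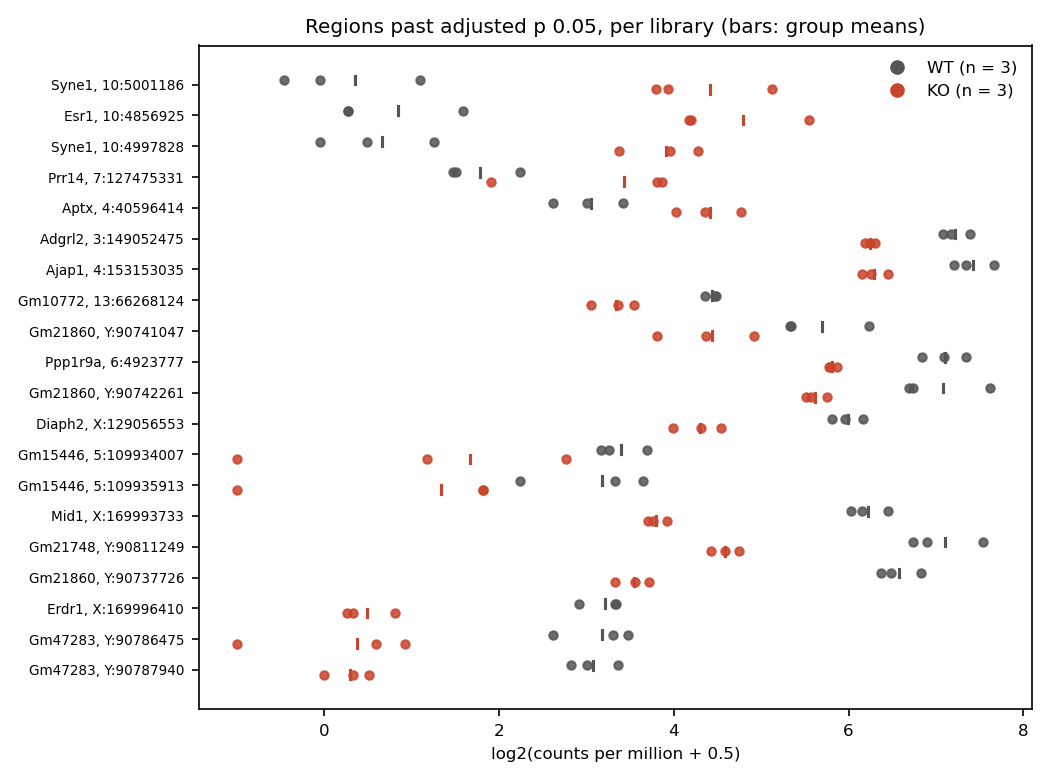
CPM, as log2 after adding 0.5, of the 20 regions past an edgeR adjusted p of 0.05, with a point per library (3 wild types in grey, 3 knockouts in red) and bars at the group means. Both regions named Syne1 lie inside Esr1; at Prr14 the groups overlap, and in the Gm15446 regions knockout replicate 7 held 0 counts.

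Regions were also summed by the gene symbol that the authors assign, including intergenic regions outside the gene. Such a sum does not measure the mark over the gene body alone. Of 15265 genes tested, 6 fell and 0 rose by an edgeR adjusted p of 0.05. The sum assigned to Mid1, a ubiquitin ligase gene at the pseudoautosomal boundary, dropped from 83.2 ± 11.8 to 19.4 ± 3.75 CPM over 4 regions (SD, n = 3). Its log2 change was -2.10 (SE 0.15, edgeR adjusted p = 2.49e-19). Most of this sum was the region at 169993733, which RefSeq places outside Mid1 (74.4 CPM in the wild types and 13.4 in the knockouts). Ppp1r9a dropped from 178 ± 24.8 to 95.04 ± 7.83 over 16 regions (log2 change -0.90, adjusted p = 1.01e-10), nearly all of it at the intron region described above: the other 15 regions summed to 53.8 ± 0.793 and 47.8 ± 10.01 CPM, a log2 change of -0.17 (exact permutation p = 0.40). On chromosome 13, Gm10772 (27 regions, log2 change -0.85, adjusted p = 1.48e-07) and the zinc finger gene Zfp997 (27 regions, -0.74, adjusted p = 4.49e-06) both fell. With promoter and genic regions only, Gm10772 did not pass (log2 change -1.05, adjusted p = 1.00, over a range from 3.23e-18 to 1.00 in 19 alternatives). Gm21748 on Y (-1.73, adjusted p = 4.81e-07) and Erdr1 on X (-0.95, adjusted p = 0.000156) were the other genes. Without the region that passed by itself, Gm21748 was left with 1 region, at a log2 change of 0.17, while the rest of Mid1 stood at -0.95, of Erdr1 at -0.72 and of Gm10772 at -0.80 (exact permutation p = 0.10 each for these 3, the smallest that 3 against 3 allows). Without adjustment 546 genes had a p under 0.05, 315 higher and 231 lower. DESeq2 called 0 higher and 7 lower, and limma-voom 1 higher and 7 lower, the 6 among them in both. Without knockout replicate 4 the count was 18, 7 higher and 11 lower, and included the 6. In simulated libraries, with genes drawn independently of each other, this test recovered 35.8% of genes changed 1.5-fold and 65.7% of those changed 2-fold.

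Because H3K9me3 forms broad domains, counts were also summed in bins of 1 Mb. At this scale most bins differed little between the genotypes: 97.6% of 2630 bins lay within 0.2 of 0 on the log2 scale, and the median standard error was 0.07. By edgeR 2 bins fell and 0 rose. The bin at 169 to 170 Mb on X, which holds Mid1, fell from 99.7 ± 10.6 to 27.7 ± 6.08 CPM (SD, n = 3; log2 change -1.85, adjusted p = 1.77e-13). The bin at 4 to 5 Mb on chromosome 6, which holds Ppp1r9a, fell from 325 ± 29.2 to 251 ± 15.6 (log2 change -0.37, adjusted p = 0.00130). This loss was that of the single Ppp1r9a region: the other 56 regions of the bin summed to 216 ± 11.6 and 219 ± 18.3 CPM, a log2 change of 0.02 (exact permutation p = 0.80). The bin did not pass without wild-type replicate 3 (log2 change -0.30, adjusted p = 0.270), over a range from 8.49e-06 to 0.270 in 18 alternatives. The last bin of Y, at 90 to 91 Mb, held 499 ± 124 CPM in the wild types and 214 ± 12.8 in the knockouts and did not pass (log2 change -1.22, adjusted p = 0.871). The largest gains by p, at 29 to 30 Mb on X (log2 change 1.01, adjusted p = 0.269) and at 4 to 5 Mb on chromosome 10, which holds most of Esr1 (0.33, adjusted p = 0.482), did not pass. Without the 2 Esr1 exonic regions in it, the latter bin had a log2 change of 0.05 (exact permutation p = 0.80). Without adjustment 42 bins had a p under 0.05, 21 in each direction, while DESeq2 called 1 higher and 3 lower and limma-voom 0 higher and 3 lower. Without knockout replicate 4 the count was 6. In simulated libraries 95.5% of bins changed 1.5-fold were recovered. Simulated bins were drawn independently of each other, so this share may not hold for the real libraries. The last 1 Mb bin of Y did not pass, though the 100 kb bins in it at 90700 and 90800 kb did (edgeR adjusted p = 5.16e-12 and 2.53e-14).

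At 100 kb, 14 bins passed, 2 higher at the Esr1 exons on chromosome 10 and 12 lower. Of the latter, 5 lay side by side or nearly so on chromosome 13 between 65900 and 66500 kb, in the zinc finger gene cluster that holds Zfp997 and Gm10772. This stretch was singled out after its values were seen, and whether the mark itself changed in it was not tested. Its 73 regions summed to 413 ± 33.2 CPM in the wild types and 245 ± 42.4 in the knockouts (SD, n = 3), a log2 change of -0.75, with every knockout below every wild type (exact permutation p = 0.10, two-sided). Its limits are those of the called 100 kb bins: in the 50 kb bins before it that start at 65700, 65750 and 65850 kb every knockout also lay below every wild type (33.2 ± 1.16 and 22.2 ± 6.12, 9.92 ± 1.91 and 4.91 ± 2.72, and 13.7 ± 3.60 and 7.98 ± 1.499 CPM). The 119 regions within 500 kb on either side, these bins included, together had a log2 change of 0.09 (exact permutation p = 0.70).

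**Figure D3:**
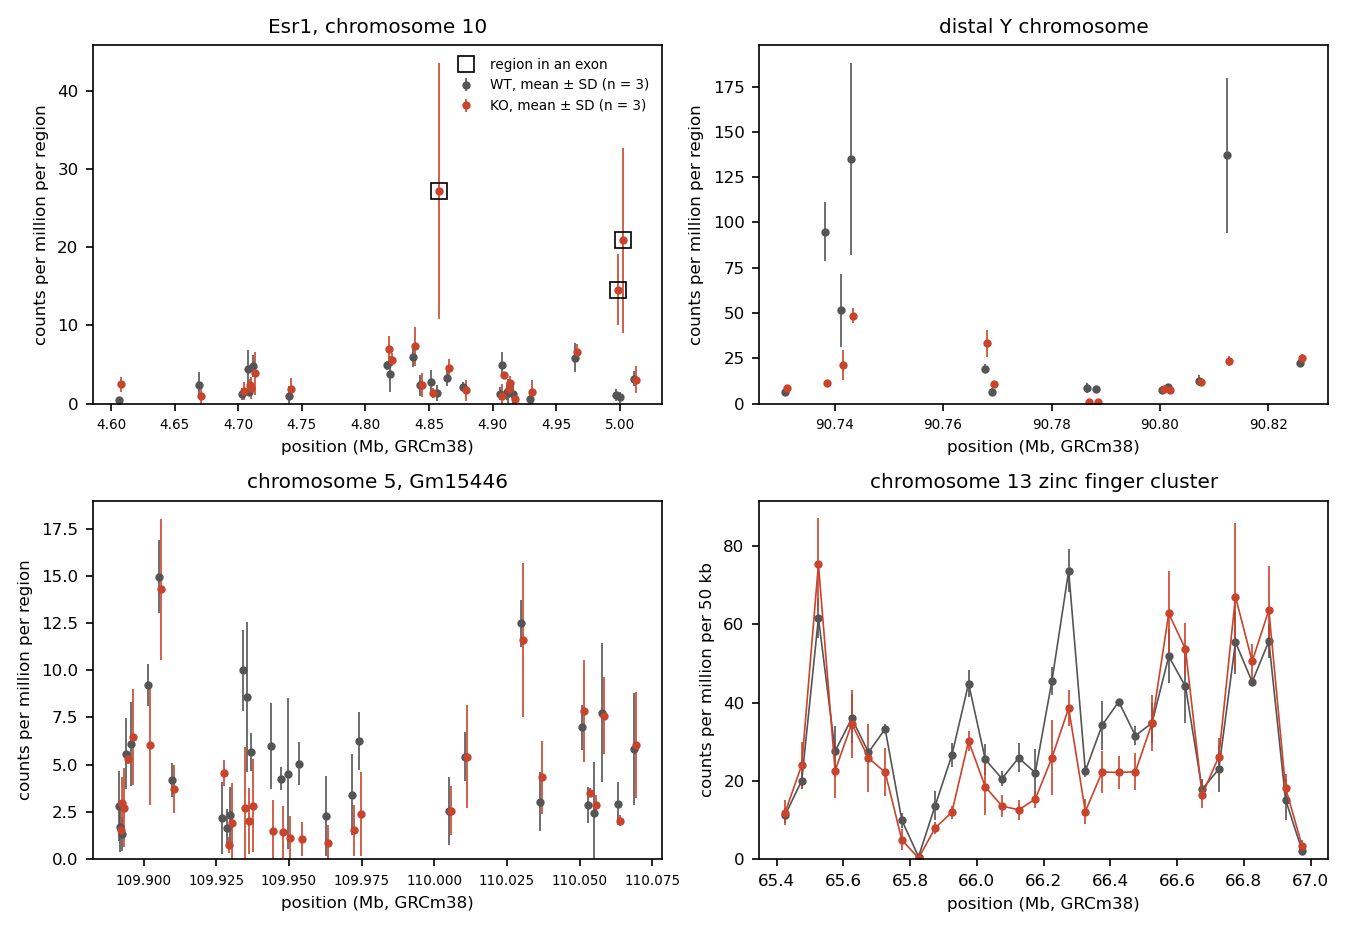
H3K9me3 in CPM (mean ± SD of 3 libraries per genotype) against position in Mb on GRCm38, per region at Esr1, at the distal Y chromosome and at Gm15446 on chromosome 5, and per 50 kb at the zinc finger cluster on chromosome 13. Squares mark the exonic regions of Esr1, where only the knockouts rise above their neighbours; on chromosome 13 the knockout means lie below the wild-type means from 65550 to 66500 kb.

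The gene lists were fixed before the data were examined. They ask whether gene sums moved for genes of muscle identity, the nuclear lamina, heterochromatin or other cell types. No list of the 26 passed fry, either for movement in a common direction (unadjusted p under 0.05 in 1 list, lowest adjusted p = 0.692) or for change in either direction (unadjusted p under 0.05 in 2 lists). Without knockout replicate 4, fry called the fibroblast list for change in either direction (adjusted p = 0.00560, against 0.603 with all libraries). The medians of the muscle lists lay near 0 on the log2 scale: -0.11 for slow fibre genes (9 genes tested), 0.04 for fast fibre genes (5), -0.11 for embryonic and cardiac sarcomere genes (10), 0.03 for MEF2 factors and fibre type regulators (27) and -0.01 for myogenic regulators (12), with a fry adjusted p of 0.983 for each. Slow fibre genes had the smallest unadjusted p for change in either direction (0.00526, adjusted p = 0.137), with Myh7, the slow myosin heavy chain, at -0.96 and Mb, the myoglobin gene, at 0.39, neither past the test over all genes (adjusted p = 1.00 each). Medians were 0.13 for oxidative metabolism genes (14, fry adjusted p = 0.983), 0.20 for glycolysis and glycogen genes (8, adjusted p = 0.692) and 0.12 for heterochromatin and H3K9 methylation genes (15), the list with an unadjusted fry p of 0.0475 (adjusted p = 0.692). In a simulated list of 24 neuronal genes fry found a 1.2-fold change (adjusted p = 0.0165), but in the 5 fast fibre genes it missed a 2-fold change (adjusted p = 0.121). The simulated genes were drawn independently of each other, so how small a change fry finds in correlated genes was not tested.

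Nuclear lamina, envelope and mechanotransduction genes, the group closest to the function of Prr14, had a median of 0.09 and a mean of 0.26 over 26 genes, 19 of them above 0 (fry adjusted p = 0.983). Prr14, the targeted gene, is itself a member and has the largest log2 change of the list (1.76). The list was not tested without Prr14. Camera with a preset correlation called this list alone, as higher than other genes (adjusted p = 0.0424), and the call was lost with an estimated correlation (adjusted p = 0.966 with an estimated correlation). Adjusted over the list alone, 2 of its genes passed, Prr14 and Syne1, against 0 over all genes tested. The Syne1 sum (log2 change 0.32) includes 9 regions inside Esr1. With these left out, a choice made after seeing the data, Syne1 stood at -0.10 (SE 0.12, edgeR adjusted p = 1.00) and the camera adjusted p of the list was 0.303. With the preset correlation camera called 8 lists without knockout replicate 4, 4 without wild-type replicate 8, and 0 without wild-type replicate 3 or 4 or knockout replicate 5, with library totals as scaling, or with promoter and genic regions only.

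Lists of other cell types, imprinted, germline and neuronal genes and of clustered gene families showed no shift by fry (adjusted p = 0.983 each). Medians were 0.01 for endothelial, -0.03 for fibroblast, -0.03 for adipocyte, 0.00 for immune, -0.05 for smooth muscle and pericyte, -0.03 for Schwann cell and nerve and -0.13 for blood genes. They were -0.02 for imprinted, 0.02 for germline and testis and -0.04 for neuronal genes. Among families chosen by symbol, medians were 0.00 for 345 zinc finger genes, -0.04 for 1041 olfactory receptor genes, -0.02 for 292 vomeronasal and trace amine receptor genes, 0.03 for 52 clustered protocadherin genes, 0.03 for 29 homeobox cluster genes, -0.02 for 174 cytochrome P450, UGT and related cluster genes and -0.06 for 7 immunoglobulin and T cell receptor segments. Adjusted over the list alone, Tcf4 passed in the list named fibroblast (log2 change 0.41) and Zfp997 among zinc finger genes. Ugt1a1 passed likewise among the cytochrome P450 and UGT genes (-0.36). Over all genes tested only Zfp997 passed. Whether Tcf4 marks fibroblasts in this muscle was not tested. The median, mean and fry direction differed in sign, in the edgeR sums or in the voom values that fry tested, for the myogenic, embryonic and cardiac sarcomere, imprinted, fibroblast, adipocyte, immune, germline, endothelial, zinc finger, vomeronasal, and cytochrome P450 and UGT lists.

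**Figure D4:**
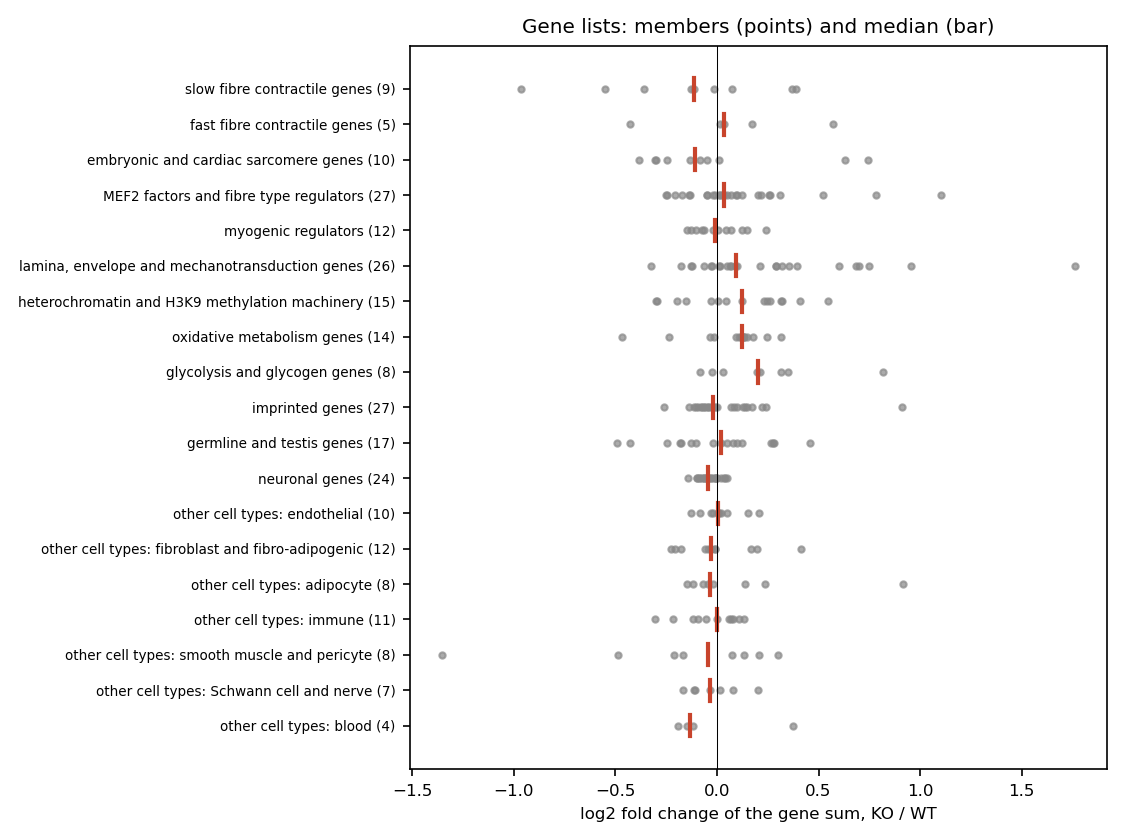
Log2 fold change of the gene sums (knockout over wild type) of each fixed gene list, with a grey point per tested gene, a red bar at the list's median and the number of genes tested in brackets. List medians lie between -0.13 and 0.20; the lamina, envelope and mechanotransduction list reaches furthest above 0, at Prr14.

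The share of counts in each kind of sequence differed between the genotypes by less than the spread between libraries. Intergenic regions held 66.9% ± 0.625 of counts in the wild types and 66.6% ± 1.07 in the knockouts (SD, n = 3; exact permutation p = 0.80). Regions within 1 kb of a start site held 7.67% ± 0.329 and 7.87% ± 0.336 (exact permutation p = 0.50). This class also holds some of the regions with the most counts, among them Gm10800, Gm10718 and Gm10722. It includes the mitochondrial regions mt-Nd6 and mt-Nd1 as well, so its share is not one of gene promoters alone. In none of 8 classes did the groups separate, while 3 did without knockout replicate 4. By chromosome, 2 of 22 separated: 7, with 5.37% ± 0.0144 and 5.41% ± 0.0108, and Y, with 0.167% ± 0.00940 and 0.139% ± 0.0125 (exact permutation p = 0.10 each, the smallest that 3 against 3 allows, adjusted p = 0.90). Without knockout replicate 4, 7 chromosomes separated, and without knockout replicate 7, 5 did. Chance alone separates 3 against 3 in 10% of cases, and more often once a library is left out. The higher counts without single libraries therefore cannot be read as effects of those libraries.

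Changed regions were more often exonic and less often intergenic than those tested. Of the 20 regions, 3 were exonic (15% against 2.08% of tested regions, Fisher's exact test, adjusted p = 0.0315), all of them the Esr1 regions, and 8 intergenic (40% against 69.1%, adjusted p = 0.0315). Neighbouring regions are not independent, and the 20 lie at few places. Among regions with an unadjusted p under 0.05, those within 1 kb of a start site made up 7.71% of the higher and 2.69% of the lower ones, against 3.81% of tested regions (Fisher's exact test, adjusted p = 1.82e-23 and 0.0110). The share of counts in these regions did not follow genotype: it was 8.01% in wild-type replicate 8, 7.95% in knockout replicate 5 and 8.17% in knockout replicate 7, against 7.35% and 7.66% in wild-type replicates 3 and 4 and 7.51% in knockout replicate 4.

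The authors' deposited table held 13 regions with an adjusted p under 0.05, 3 higher and 10 lower in the knockouts. These were the Esr1 exonic regions, the sites in Ppp1r9a and assigned to Ajap1, Adgrl2 and Diaph2, and regions of the X and Y ends, and all 13 were among the 20 called here, with the same sign. The authors' deposited table had 7924 regions with an unadjusted p under 0.05 (3.91% of all regions), 3268 higher and 4656 lower. Here 3113 were higher and 2790 lower (together 3.84% of the tested regions). Log2 fold changes in the authors' deposited table had a median of -0.05, both over all regions and over those tested here, against 0.00 for the values fitted here. Across the 153789 tested regions, which are not independent, the log2 fold changes of the authors' deposited table and those fitted here had a correlation of 0.999.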

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

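The fits without robust weighting, those with the mitochondrial share as a covariate, and the gene lists without regions inside Esr1 were chosen after seeing the data; the other alternatives were planned. No region, gene or bin past the threshold changed direction under any alternative. Of the 20 regions, 7 passed in every alternative that tested them, as did 2 of 6 genes (Mid1 and Gm21748) and 1 of 2 bins (169 to 170 Mb on X). The count of regions was 11 with X and Y left out and 12 without regions under 500 bp, both with fewer regions tested, and 16 to 22 otherwise; leaving out single libraries gave 15 to 19. The count of genes was 2 with an added fold of 2, 3 with X and Y left out and 10 with the mitochondrial covariate (2 higher and 8 lower, the 6 included; the cause was not tested). Without single libraries it ran from 6 to 18, the highest without knockout replicate 4. The count of 1 Mb bins was 4 with DESeq2, 1 with an added fold of 2, 1 with X and Y left out, 14 with 100 kb bins, which separate short stretches from their surroundings, and 4 with the covariate; without single libraries it was 2 to 6, the highest without knockout replicate 4. The cause was not tested for DESeq2 or the covariate. Camera with its preset correlation called 1 list where fry called 0; fry for a common direction called 0 whichever library was left out, and fry for change in either direction called 1, the fibroblast list, without knockout replicate 4 (adjusted p = 0.00560). Prr14 and Mef2c together gave 0 to 1 called regions without single libraries, and Prr14 was lost with the covariate (edgeR adjusted p = 0.530, over a range from 8.62e-05 to 1.00). Classes of sequence whose shares separated numbered 0 to 3 without single libraries (3 without knockout replicate 4), chromosomes 1 among regions with a mean of 20 counts, where fewer regions count, and 2 to 7 without single libraries (7 without knockout replicate 4, 5 without knockout replicate 7). Groups also separate by chance more often once a library is left out. Taking changed regions at an unadjusted p gave 4 classes that differed in place of 2. With the depth and spread of these libraries, simulated 2-fold changes were recovered in 7.46% of regions and 65.7% of gene sums; depth and spread were not varied apart. No GC correction was run, since no genome sequence was used here. No paired analysis was possible because the labels pair no mice, and only replicate number 4 occurs in both genotypes.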

Other observations

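All tests in this part except the splits of the libraries were chosen only after the result was seen.

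The counts over Esr1 exons rose while the introns between them did not. The 3 exonic regions summed to 3.17 ± 0.418 CPM in the wild types and 62.7 ± 32.0 in the knockouts (SD, n = 3; exact permutation p = 0.10, the smallest that 3 against 3 allows). A gain of the mark over the whole locus is argued against by the 17 intron regions, whose log2 change was 0.15. A candidate explanation is a second copy of Esr1 coding sequence without introns, such as a transgene carrying part of the receptor, for which a flat intron sum of 0.15 is what would be seen. Whether the knockout mice carry such a transgene is not given in the sources used here, and a change of H3K9me3 at these exons alone was not tested.

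The 4 dispersed sites, in Ppp1r9a and assigned to Ajap1, Adgrl2 and Diaph2 (log2 change of their sum -1.19) and the 8 regions of the X and Y ends (-2.11) fell together. A difference in sex or Y number is argued against by the ratio of Y shares below 90 Mb, 1.00, and a loss over the surroundings by the summed neighbours within 100 kb of the sites assigned to Ajap1 (31 regions, 0.075), Adgrl2 (11 regions, 0.31) and Diaph2 (only 4 regions, 0.32), while at the Ppp1r9a site (14 regions, -0.16) it cannot be told apart, since knockout replicate 4 stood at -0.51 to the wild types there. Wild-type replicate 3 exceeded the other wild types at the 4 sites (median ratio 1.255) as it did at the X and Y ends (1.40), and 0% of 10000 sets of 4 regions matched on counts had as high a median (median of sets 0.946). Since the sites were picked for wild types above knockouts and the sets were not, the 0% decides nothing, and reads from 1 shared sequence source at the dispersed sites and the X and Y ends cannot be told apart. A change of H3K9me3 at the sites themselves stays open and was not tested.

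On chromosome 5, between 109929974 and 109974629, knockout replicate 7 held 0 counts over 11 neighbouring regions around Gm15446, where the wild types held 253, 280 and 220. Low depth is argued against by the 233 counts expected there in this library. A stretch missing from the genome of this animal is a candidate explanation: the 10 regions on each side held a log2 ratio of -0.32 to the wild types. Knockout replicates 4 and 5 held 156 and 86 counts, so a loss of H3K9me3 in the knockouts cannot be told apart, since the highest knockout count of 156 lies below every wild type but far above 0.

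The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. For regions the real split gave 20 calls and the highest other 1, so 1 of the 10 splits, the real included, gave as many. For genes the real split gave 6, the highest other 281, and 3 of the 10 gave as many. For bins of 1 Mb the real split gave 2, the highest other 147, and 2 of the 10 gave as many. The split with 281 genes and 147 bins sets wild-type replicates 3 and 4 and knockout replicate 4 against wild-type replicate 8 and knockout replicates 5 and 7, which points to a structure of the samples that crosses the genotypes. Along it, the share of counts within 1 kb of a start site was 7.35%, 7.66% and 7.51% in the former and 8.01%, 7.95% and 8.17% in the latter, and the mitochondrial share was 0.174%, 0.189% and 0.146% against 0.366%, 0.248% and 0.612%. These shares overlap, since the mitochondrial regions mt-Nd6 and mt-Nd1 are annotated within 1 kb of a start site. The overlap is only a small part of the start-site share. From wild-type replicate 4 to knockout replicate 5 that share went from 7.66% to 7.95%, and the mitochondrial share only from 0.189% to 0.248%. At mt-Nd6, knockout replicate 4 held 3689 counts and knockout replicate 7 held 14312.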
